A study of Homo sapiens with 28 samples.

How the data were processed

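The analysis began from gene tables deposited by the authors. The deposited estimated counts are read numbers per gene symbol, summed from transcripts and not scaled to a common total. They are not all whole: per library, 41.0 to 47.5% of the nonzero values were whole numbers. A TPM table, scaled by the authors so that each library sums to the same total, and a table of effective length in bases per gene and library, which the authors supplied beside it, came with them. Salmon 0.11.3, FastQC 0.11.7 and genome build GRCh38 were used upstream, per the submitters' processing notes; the annotation release, read filters and Salmon settings are not given in the sources used here. Within each library, estimated count divided by TPM times effective length was constant, so the 3 tables describe the same quantification. All 56809 symbols matched GENCODE release 29, whose positions are used. ERCC spike-in RNA was not analysed here. Libraries were made from polyadenylated RNA amplified by PCR and read from 2 ends, per the labels.

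Genotype, treatment, replicate number and batch were taken from the labels. The untreated and LPS libraries that share a genotype and replicate number were read as 1 clone. That pairing was checked once on genes centred within each group: the correlation between the 2 libraries of a clone was 0.203 to 0.441, and all 14 clones correlated best with their own partner among clones of the same genotype. In the 4 genotypes with 2 clones, centring makes the other correlation the negative of the own, so these give only 1 check of sign per genotype. Replicate pairs within a group correlated at 0.952 to 0.981 (20 pairs) and none were identical. The share of counts on mitochondrial messenger RNA was 4.20 to 7.23% per library, and that of the 10 highest genes 9.98 to 14.3%. Marker lists for other cell types had these highest mean values: NKG7 339.8 TPM (T and NK cells), PPBP 1.95 (platelets), KRT8 1.27 (epithelial) and PDGFRB 0.51 (fibroblasts). Some results for single genes are not reported here. IL7R (14.2 TPM) and TRAC (3.86 TPM) followed NKG7. Whether the NKG7 level belongs to the line or to other material was not settled.

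Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18624, and scaled by TMM. A robust quasi-likelihood model held 12 groups of genotype and treatment and batch as an additive term, with 14 residual degrees of freedom and a biological coefficient of variation of 31.7%. There were 22 comparisons: LPS against untreated in each genotype, each knockout against CTR without and with LPS, the difference in LPS response between each knockout and CTR, and that between p65 and the mean of the other 4 knockouts. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Log2 folds are given with the standard error of the model, CPM are TMM-scaled, and the log CPM behind clone means used a prior count of 2. Alternatives were DESeq2 1.42.0, limma voom 3.58.1 with clone as a random effect (consensus correlation 0.355), other size factors, an effective length offset, no filter, no batch term, batch C alone, each clone left out, and each clone as a block (8 residual degrees of freedom, coefficient of variation 21.0%). The comparisons, gene lists and these alternatives were fixed before the data were examined.

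The 18 fixed gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, and with fry. A list was taken as passing where the estimated correlation kept the call. The lists covered NF-kB feedback and inhibitors, cytokines, chemokines, interferon-stimulated genes, MHC class I, MHC class II, adhesion and costimulation, survival and apoptosis, TLR4 signalling, monocyte differentiation, promyelocyte granule proteins, antimicrobial and oxidative burst genes, proliferation, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and integrated stress, immediate early and heat shock genes, and mitochondrial messenger RNA. Granule genes had a median log2 fold of 0.95 in cREL against CTR with LPS (estimated correlation, adjusted p = 0.0779), and mitochondrial messenger RNA one of −0.67 in p65 against CTR without LPS (adjusted p = 0.609). For each knockout a further set of LPS-induced genes was taken from the LPS effect averaged over the 4 other knockouts (adjusted p under 0.05, log2 fold above 1), so that neither CTR nor that knockout chose the genes.

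Genes were named by a rule. The 5 targeted genes were read everywhere. Each comparison gave up to 6 genes from either end by log2 fold (10 for CTR with LPS and for p65, 3 for the other differences) among those that passed with a mean of at least 5 CPM and a gene symbol, and, for LPS effects, the same sign in every clone. Each list gave up to 4 passing members of lowest adjusted p and up to 2 others of highest CPM. Genes outside the rule are marked as chosen after their values were seen.

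The scripts were tested on simulated data with 100 changed genes at each of 2 sizes, log2 1 and 2. With LPS in CTR, 35 and 79 were recovered among 17806 genes tested, with 122 called in all, of which 8 were unchanged. With LPS in p50, 23 and 62 were recovered (89 called, 4 unchanged), and for p65 against CTR with LPS 29 and 74 (107 called, 4 unchanged). For p50 against CTR with LPS, 19 and 67 were recovered (93 called, 7 unchanged), and for the p65 minus CTR difference 8 and 55 (65 called, 2 unchanged). Of 40 random sets of 25 genes, at most 1 passed with camera, at most 1 with an estimated correlation and 1 to 4 with fry. The simulated genes were drawn independently, with no correlation between genes and no clone or batch effect. These rates therefore do not cover lists of correlated genes, or gene tests in data with clone or batch effects.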

Results

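Polyadenylated RNA was sequenced from 28 libraries of U937, a human monocytic cell line, to ask what each NF-kB subunit contributes to gene expression with and without lipopolysaccharide (LPS). LPS is a component of the outer membrane of Gram-negative bacteria that signals through the receptor TLR4. NF-kB is a family of transcription factors made of the subunits p50, p52, p65, cREL and RELB, encoded by NFKB1, NFKB2, RELA, REL and RELB. Each subunit had been targeted by CRISPR in separate clones. The libraries came from 14 clones, each sequenced once untreated and once with LPS at 500 ng/ml, at 6 h. There were 3 control clones made with non-specific guide RNAs (CTR), 3 p65 knockout clones, and 2 clones of each other knockout. The labels place the clones in 3 sample batches, and batch A holds no control clone. The estimated counts summed to between 12643438 and 22122428 per library, and between 22783 and 25837 genes per library had a value above 0. The p-values of gene tests measure the spread between clones of a group or, with each clone as a block, the spread of their LPS response. The main model does not pair the 2 libraries of a clone and treats them as independent. Its 14 residual degrees of freedom may therefore overstate those between clones. The p-values of knockouts against CTR may then be too small. Camera p-values compare the genes of a list with the other genes tested. The intervals on count ratios cover counting error only, because the reads came from PCR without molecular identifiers.

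The messenger RNA of the targeted genes was read first, in every library. In GRCh38, with GENCODE release 29, NFKB1 lies on chromosome 4 from 102501329 to 102617302 and NFKB2 on chromosome 10 from 102394110 to 102402529. RELA lies on chromosome 11 from 65653596 to 65663094, REL on chromosome 2 from 60881521 to 60931610, and RELB on chromosome 19 from 45001430 to 45038198. The sites cut by the guides are not given in the labels, and a small deletion need not lower the messenger RNA, so these levels need not follow the labels. NFKB1 was lower in the p50 clones than in CTR with LPS, at 5.46 ± 1.93 against 12.7 ± 2.15 TPM (mean ± SD, n = 2 and n = 3), with a log2 fold of −1.70 ± 0.31 (SE; edgeR adjusted p = 0.0387; lower in 2 of 2 clones). Without LPS it stood at 3.25 ± 0.71 against 6.94 ± 2.08 TPM (SD) and did not pass the test (edgeR adjusted p = 0.44).

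RELA stood at 3.20 to 8.19 TPM in the 4 libraries of p65 replicates 2 and 3, below all 22 libraries of the other genotypes, which held 23.2 to 38.3 TPM. The libraries labelled p65 replicate 1 did not share this low level. They held RELA at 43.7 TPM untreated and 52.1 TPM with LPS, above every other library in TPM. In CPM, which are not scaled by length, they held 53.6 and 58.3. Those values lay within the other genotypes, which ran from 43.9 to 65.7 CPM. Because the RELA level of p65 replicate 1 also enters the batch A term of the model, no fitted RELA fold is given. The other targeted genes did not pass the test in their own knockout. With LPS, REL stood at 4.80 ± 3.27 TPM in cREL against 13.7 ± 1.11 in CTR (SD; log2 fold −1.15, edgeR adjusted p = 0.23), and NFKB2 at 1.79 ± 0.24 TPM in p52 against 6.51 ± 1.20 (SD; log2 fold −1.74, edgeR adjusted p = 0.23). RELB stood at 15.3 ± 5.61 TPM in RELB against 21.4 ± 4.19 in CTR (SD; log2 fold −0.82, edgeR adjusted p = 0.65), and 2 of the 4 RELB libraries lay below the lowest control library of the same treatment. The levels of NFKB1, NFKB2 and RELB do not check the labels, because with LPS untargeted knockouts were low as well. NFKB2 averaged 1.15 TPM in p50, 0.993 in cREL and 2.48 in p65, and NFKB1 6.68 in cREL, 7.06 in p52 and 7.18 in p65. RELB averaged 3.85 to 6.63 TPM in p50, p52, p65 and cREL, below its mean in the RELB clones. REL, by contrast, had its lowest mean in cREL, against mean values of 8.98 to 13.0 TPM in the other knockouts, although single libraries of p50 and RELB overlapped cREL.

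**Figure D1:**
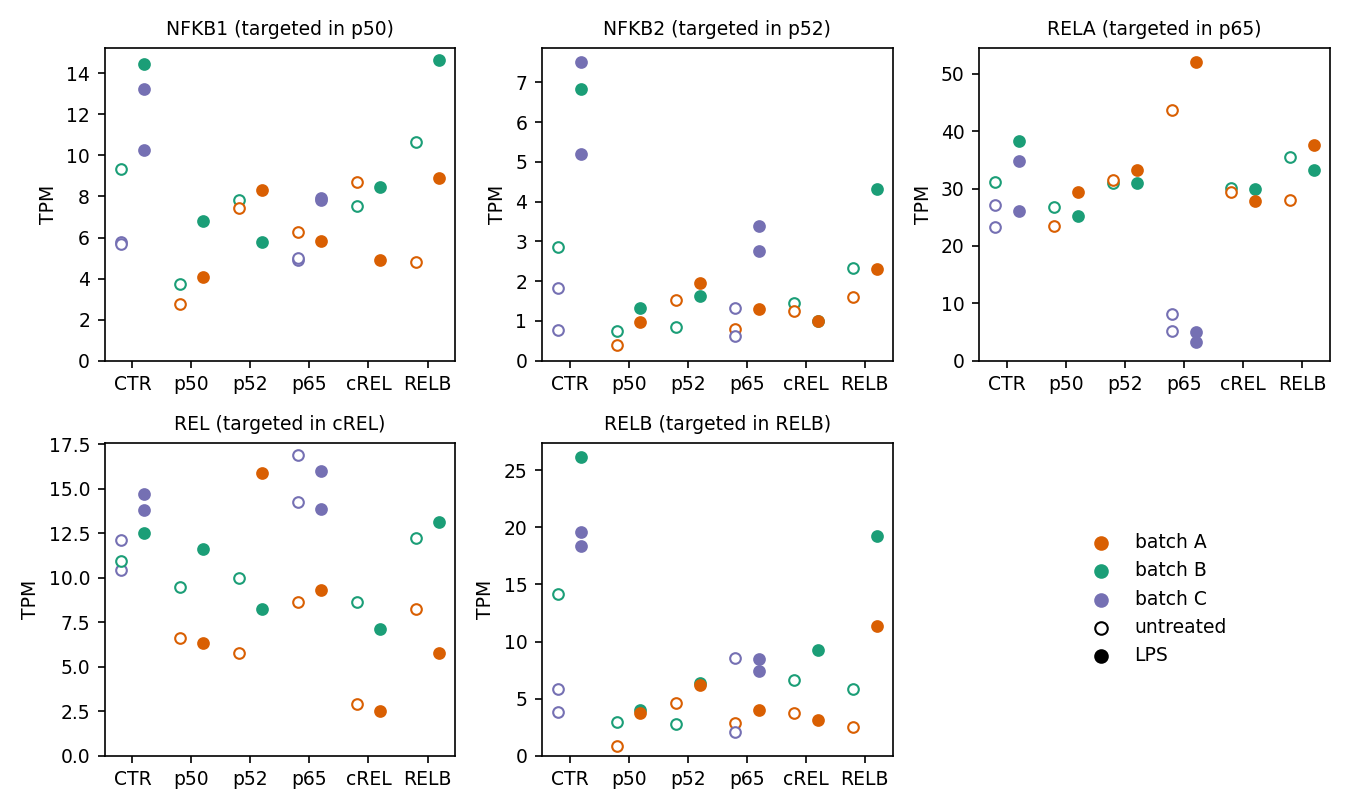
TPM of NFKB1, NFKB2, RELA, REL and RELB in each of the 28 libraries, grouped by genotype, with open symbols for untreated and filled symbols for LPS libraries and colours for sample batches. RELA in the libraries labelled p65 replicate 1 sits at 43.7 and 52.1 TPM, whereas the other p65 libraries lie between 3.20 and 8.19 TPM.

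LPS raised chemokine, cytokine and NF-kB feedback genes in the control clones. IL1B, which encodes the inflammatory cytokine interleukin-1 beta, rose from 9.36 ± 5.39 to 302 ± 100 CPM (SD, n = 3), a log2 fold of 5.05 ± 0.53 (SE; edgeR adjusted p = 4.1e-05). CXCL8, a chemokine that attracts neutrophils, rose from 71.7 ± 49.3 to 1069 ± 639 CPM (SD; log2 fold 3.93, edgeR adjusted p = 4.2e-05). CCL4, a chemokine for monocytes and T cells, had 4 counts over the 3 untreated libraries and 4229 over the LPS libraries, a ratio of 988 with a 95% counting interval from 386 to 3629. ICAM1, an adhesion molecule, rose from 97.3 ± 13.9 to 616 ± 247 CPM (SD; log2 fold 2.56), and SOD2, the mitochondrial superoxide dismutase, from 120.1 ± 54.3 to 1124 ± 485 CPM (SD; log2 fold 3.30). PTGS2, which encodes cyclooxygenase-2, rose by a log2 fold of 5.04 ± 0.56 (SE), and CXCL10 by 5.95 ± 1.01. Each of these genes was higher with LPS in 3 of 3 control clones.

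By list, 10 of 20 measured chemokine genes rose over all genes tested and 14 adjusted over the list alone, with a median log2 fold of 3.73 (camera, estimated correlation, adjusted p = 1.8e-07). CXCL2 (4.88), CCL3 (4.31), CCL3L1 (5.397), CCL4L2 and CCL8 were among them; reads of CCL3 and CCL3L1, and of CCL4 and CCL4L2, may be split between near-identical copies. Of the 17 genes for NF-kB feedback and inhibitors, 8 rose, and 12 adjusted over the list alone, with a median of 1.31 (estimated correlation, adjusted p = 2.6e-06). They included NFKBIA, the inhibitor that holds NF-kB in the cytoplasm (2.06 ± 0.26, SE), the ubiquitin-editing enzyme gene TNFAIP3 (3.09 ± 0.36), NFKBIZ (3.34 ± 0.34) and the ribonuclease gene ZC3H12A (2.80 ± 0.32). Of 18 cytokine genes, IL1B and TNF (2.51 ± 0.35) rose, and 9 adjusted over the list alone, with a median of 2.08 (adjusted p = 4.0e-06). Among adhesion and costimulatory molecules, ICAM1 and TNFRSF9 (2.87) rose out of 18, and 4 adjusted over the list alone (median 0.79, adjusted p = 1.5e-04).

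Smaller list changes in CTR also held with an estimated correlation. PTGS2 and PLAU (0.92) rose out of 16 antimicrobial and oxidative burst genes, and 8 adjusted over the list alone (median 0.69, adjusted p = 3.4e-04). SOD2 and CFLAR (0.84), an inhibitor of caspase-8, rose out of 20 survival and apoptosis genes, with 4 adjusted over the list alone (median 0.23, adjusted p = 1.9e-04). IRAK2 (1.39) and TRAF3 (1.02) rose out of 29 TLR4 signalling genes, with 7 adjusted over the list alone (median 0.21, adjusted p = 0.0011). EGR1 (3.11), IER3 (3.50) and ATF3 (1.32) rose out of 15 immediate early and heat shock genes, with 3 adjusted over the list alone (median 0.60, adjusted p = 4.6e-04). The glucose transporter gene SLC2A3 (1.64) and PFKFB3 (0.77) rose out of 26 glycolysis and hypoxia genes, with 2 adjusted over the list alone (median 0.11, adjusted p = 0.042). For the 18 unfolded protein and integrated stress response genes, of which ATF3 rose and 1 passed adjusted over the list alone, and the 17 MHC class I genes, of which 0 rose and 2 adjusted over the list alone, the preset-correlation call was lost (adjusted p = 0.24 for each with an estimated correlation). The stress response list passed with each clone as a block (adjusted p = 0.0249). The lists for MHC class II, monocyte differentiation, promyelocyte granules, proliferation, cholesterol synthesis and mitochondrial messenger RNA did not pass.

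The 47 interferon-stimulated genes had a median log2 fold of 1.53 with LPS in CTR, and all 47 were higher by sign. Their response differed between control clones, however, with a mean log2 difference of 2.09 in CTR replicate 1, 0.37 in replicate 2 and 1.17 in replicate 3. edgeR called 0 of the 47 over all genes and 2 adjusted over the list alone, and the list call was lost with an estimated correlation (adjusted p = 0.0977). With each clone as a block, 9 were called and the list passed (estimated correlation, adjusted p = 0.00824). Without CTR replicate 1, an omission chosen after the result was seen, the median was smaller, 0.58, edgeR called 0 of the 47, and the list passed (estimated correlation, adjusted p = 0.028). In the 11 knockout clones the mean response of these genes lay between −0.17 and 0.34.

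In total, edgeR called 76 of 18624 genes with LPS in CTR, 75 higher and 1 lower (AC207130.1, −1.05, named after its value was seen). The clones pair the libraries, and with each clone as a block edgeR called 236 genes, 225 higher and 11 lower, including 73 of the 76. The count was 50 without a batch term, 29 without CTR replicate 1 and 21 without CTR replicate 3.

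**Figure D2:**
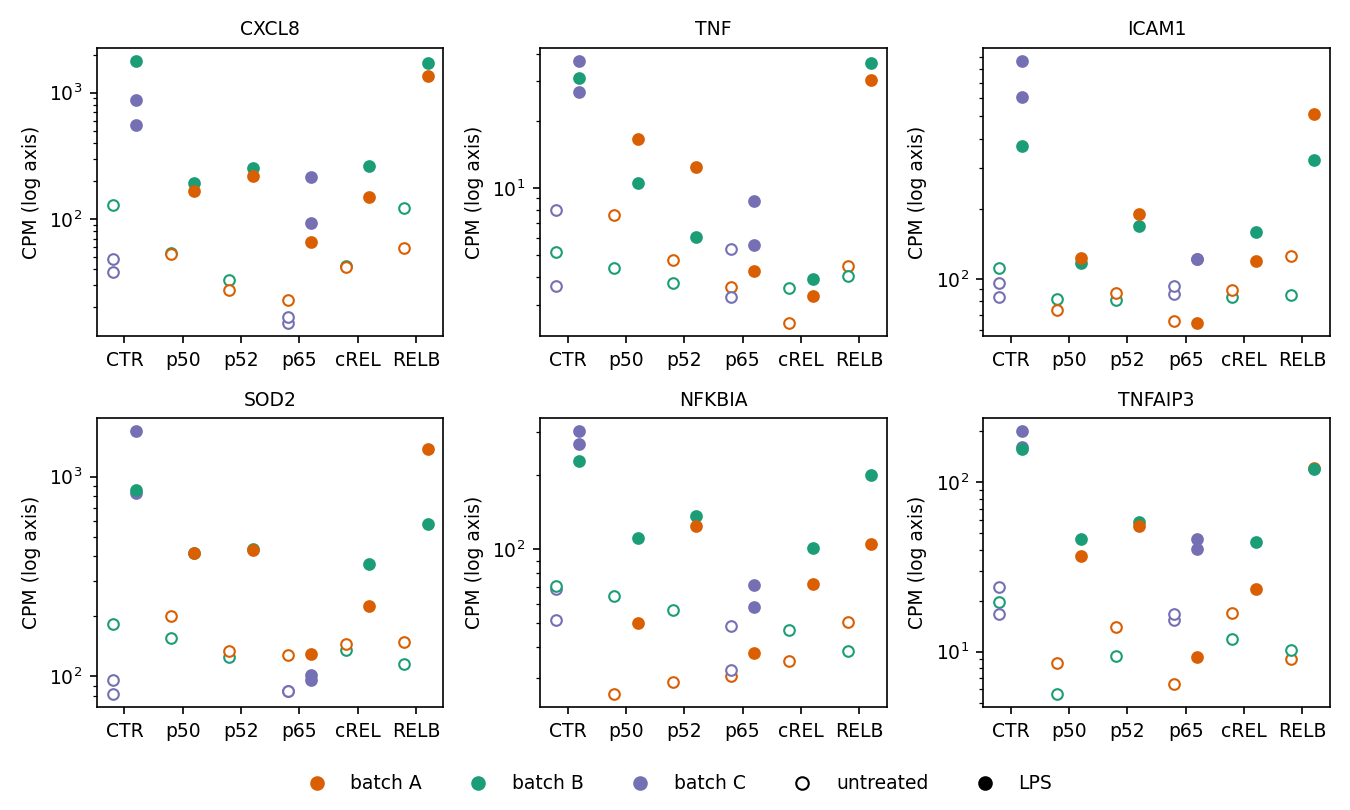
CPM of CXCL8, TNF, ICAM1, SOD2, NFKBIA and TNFAIP3 in each library on a log axis, grouped by genotype, with open symbols for untreated and filled symbols for LPS libraries and colours for sample batches. In CTR, CXCL8 averages 71.7 CPM untreated and 1069 CPM with LPS, and in RELB 90.4 and 1527 CPM.

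**Figure D3:**
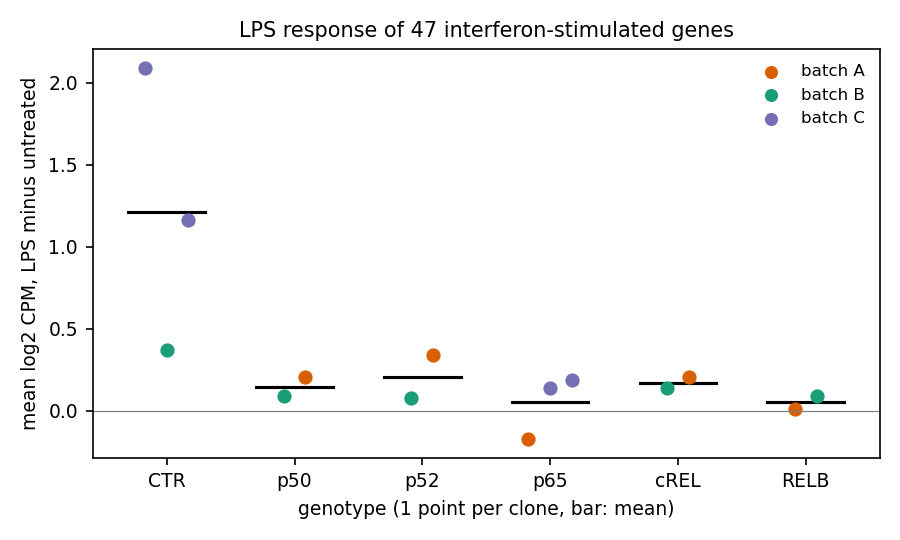
Mean log2 LPS-minus-untreated difference of the interferon-stimulated genes in each of the 14 clones. CTR replicates 1 and 3 sit at 2.09 and 1.17, CTR replicate 2 at 0.37, and the knockout clones between −0.17 and 0.34.

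In the p50, p52, p65 and cREL knockouts, few genes passed the test with LPS. They were the chemokine genes CCL4, CCL4L2, CXCL2 and CXCL8, with NFKBIZ and AC009086.2. In p50, 3 genes rose: CCL4 (5.50 ± 0.58, SE), NFKBIZ (2.46 ± 0.41), and CCL4L2, which was listed at 0 without LPS and rose at least 44.3-fold against a floor of 3 counts over the group. In p52, 4 genes rose: CCL4 (489 counts over the group against 2, ratio 260, 95% counting interval 71.7 to 2156), CCL4L2 (5.38), CXCL8 (2.98 ± 0.49) and NFKBIZ (2.50). In p65, 5 genes rose: CXCL2 (3.27 ± 0.47), CXCL8 (2.86 ± 0.40), CCL4 (4.06), CCL4L2 (at least 21.5-fold) and AC009086.2 (7.82, named after its value was seen). In cREL, CCL4 (414 counts against 3, ratio 121, interval 41.2 to 591) and CCL4L2 (5.23) rose. Each of these genes except AC009086.2, whose clones were not compared here, was higher with LPS in each clone of its genotype. The chemokine list passed in all 4, with medians of 1.66 in p50, 2.25 in p52, 1.82 in p65 and 1.46 in cREL (estimated correlation, adjusted p = 1.7e-04, 7.0e-05, 9.1e-05 and 4.2e-05); 2, 3, 4 and 2 of 20 members rose over all genes and 6, 9, 8 and 7 adjusted over the list alone.

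The NF-kB feedback list also passed in these 4 knockouts, with medians of 0.40, 0.73, 0.22 and 0.24 for p50, p52, p65 and cREL (estimated correlation, adjusted p = 0.0112, 8.1e-04, 0.0222 and 0.0357); 1, 1, 0 and 0 of 17 members rose over all genes and 3, 6, 5 and 4 adjusted over the list alone. With the clone block the feedback calls ended in p65 (adjusted p = 0.112) and cREL (adjusted p = 0.130). The cytokine list passed in cREL (median 0.42, adjusted p = 0.026; 0 of 18 over all genes and 1 adjusted over the list alone). The immediate early list passed in p52 (median 0.40, adjusted p = 0.0229) but not with the block (adjusted p = 0.0939), whereas the antimicrobial list in p50 (median 0.35, adjusted p = 0.116) passed only with it (adjusted p = 0.0491). CXCL8 lost its call with the block in p52 (edgeR adjusted p = 0.297) and in p65 (edgeR adjusted p = 0.349). The counts with the block were 6 in p50, 3 in p65 and 4 in cREL. In p65 these 3 were among the 5 genes called without the block, so AC009086.2 lost its call as well as CXCL8. Without p50 replicate 2 the count in p50 was 1, and without either p52 clone that in p52 was 1. It was 0 in p65 without p65 replicate 2 or replicate 3, and 1 in cREL without cREL replicate 1. Without a batch term it was 1 in p52, 0 in p65 and 1 in cREL.

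The RELB knockout clones answered LPS with many of the genes that rose in CTR. IL1B rose from 15.9 ± 6.12 to 492 ± 94.4 CPM (SD, n = 2; log2 fold 4.93 ± 0.63, SE; edgeR adjusted p = 9.9e-04), CXCL8 from 90.4 ± 44.5 to 1527 ± 251 CPM (SD; 4.14 ± 0.51, SE) and ICAM1 from 105 ± 28.3 to 418 ± 133 CPM (SD; 1.99 ± 0.29, SE). CCL4 had 3 counts without and 2100 with LPS over the group, a ratio of 685 with a counting interval from 234 to 3326. CXCL2 (5.36), PTGS2 (4.60), TNF (2.98), SOD2 (2.86), TNFAIP3 (3.65), ZC3H12A (2.71), NFKBIZ (2.25), NFKBIA (1.63), IRAK2 (1.60) and PLAU (1.27) also rose. All were higher in 2 of 2 clones. Of 20 chemokine genes 5 rose, and 10 adjusted over the list alone (median 3.23, estimated correlation, adjusted p = 1.7e-06). Of 17 feedback genes 4 rose, and 9 adjusted over the list alone (median 1.19, adjusted p = 2.6e-04). The lists for cytokines (median 1.01, adjusted p = 2.6e-04), adhesion (0.37, 6.9e-04), survival (0.19, 4.1e-04), antimicrobial genes (0.73, 4.1e-04), immediate early genes (0.52, 4.1e-04), cholesterol synthesis (median 0.17, adjusted p = 0.0136) and glycolysis (median 0.19, adjusted p = 0.00758) passed too, as did TLR4 signalling (median 0.13, adjusted p = 0.0211; 0.0538 with the block). The stress response list passed only with the block (adjusted p = 0.00480; 0.0818 without).

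edgeR called 24 genes in RELB, 23 higher and 1 lower (LSM12P1, a pseudogene, −8.76, named after its value was seen). All 23 were among the 75 that rose in CTR, where independent lists would share 0.0926. With the clone block 81 genes were called, 80 higher and 1 lower, including all 24. The count was 14 without a batch term, 8 without RELB replicate 1 and 11 without RELB replicate 2.

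The difference in LPS response between each knockout and CTR was tested directly. In p65, the responses of 3 genes were smaller than in CTR: ICAM1 by a log2 difference of −2.26 ± 0.33 (SE; edgeR adjusted p = 0.0131), SOD2 by −3.15 ± 0.44 (edgeR adjusted p = 0.0131) and PTGS2 by −4.47 ± 0.74 (edgeR adjusted p = 0.0382). With LPS, ICAM1 reached 103 ± 33.3 CPM (SD, n = 3) in p65 and SOD2 reached 109 ± 17.9 CPM, against 616 and 1124 CPM in CTR. The 3 p65 clones include the clone labelled p65 replicate 1, which holds RELA messenger RNA. With the clone block 14 genes were called, 1 larger and 13 smaller, including ICAM1 and PTGS2 but not SOD2 (edgeR adjusted p = 0.067). The count was 0 when any 1 of CTR replicate 1, CTR replicate 3 or the 3 p65 clones was left out, 0 in batch C alone and 1 with an effective length offset.

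For the other knockouts edgeR called 0 genes in this difference, with 550 (p50), 474 (p52), 560 (cREL) and 398 (RELB) genes at an unadjusted p under 0.05. DESeq2 called 6, 7, 4 and 3, and the clone block 2, 1, 0 and 0. Without p50 replicate 1 the p50 count was 2; 1 gene was called in p50 or in cREL without CTR replicate 2, 1 in cREL without cREL replicate 2 and 1 in RELB without CTR replicate 1. Between p65 and the mean of the other 4 knockouts edgeR also called 0 genes (270 unadjusted; DESeq2 2; clone block 1; 1 without p50 replicate 2).

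As lists, the LPS-responsive genes rose less in p50, p52, p65 and cREL than in CTR. The chemokine response was smaller by a median log2 difference of −2.16 in p50, −1.68 in p52, −1.78 in p65 and −1.80 in cREL (estimated correlation, adjusted p = 0.00732, 0.0103, 0.0158 and 0.00851), and 17, 18, 18 and 17 of 20 members were smaller by sign. With the clone block the chemokine call ended in p52 (adjusted p = 0.0569) and p65 (adjusted p = 0.0846). The cytokine response was smaller by −1.41, −1.44, −1.23 and −1.16 (adjusted p = 0.00732, 0.00943, 0.00314 and 0.0306). The NF-kB feedback response was smaller by −0.87, −0.70, −1.02 and −1.10 (adjusted p = 0.00732, 0.0444, 0.00279 and 0.00652), and in p52 the call ended with the block (adjusted p = 0.0945). Adhesion molecules were smaller by −0.52, −0.57, −0.62 and −0.71 (adjusted p = 0.026, 0.021, 0.00314 and 0.00851), with 1 gene over all genes, in p65. Over all genes 0 chemokine, cytokine or feedback genes passed in any of the 4 knockouts. Adjusted over the list alone, 6, 0, 1 and 2 chemokine genes, 0, 1, 2 and 1 cytokine genes, and 0, 0, 7 and 6 feedback genes did. Interferon-stimulated genes differed by medians of −1.43, −1.23, −1.65 and −1.43, and these calls were lost with an estimated correlation (adjusted p = 0.32, 0.347, 0.156 and 0.31); in p65 the list passed with the block (adjusted p = 0.0262). Without CTR replicate 1 these medians shrank to −0.53, −0.45, −0.56 and −0.63 (estimated correlation, adjusted p = 0.196, 0.299, 0.0657 and 0.259). Immediate early and heat shock genes, a list fixed as a sign of handling or RNA quality, moved the same way, by −0.56 in p50, −0.34 in p65 and −0.56 in cREL (adjusted p = 0.0344, 0.035 and 0.0122), and did not pass in p52 (−0.19, adjusted p = 0.347). With the block, the calls in p50 (adjusted p = 0.0664) and p65 (adjusted p = 0.0846) ended. In RELB no list passed with an estimated correlation (feedback median −0.43, adjusted p = 0.705; interferon-stimulated genes −1.49, adjusted p = 0.705, and −0.71 without CTR replicate 1).

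A set of LPS-induced genes was also chosen for each knockout without its own libraries or those of CTR. Over 24 such genes, the mean LPS response per clone was 1.31 ± 0.68 (SD, n = 3) in p65 against 4.06 ± 0.65 (n = 3) in CTR, a fitted difference of −2.50 (camera, estimated correlation, adjusted p = 1.0e-05). The clone labelled p65 replicate 1 had the lowest response of the p65 clones, 0.53. The difference was −1.97 in p50 over 23 genes (1.90 ± 0.09 against 3.94 ± 0.71), −1.81 in p52 over 21 genes (2.34 ± 0.14 against 4.14 ± 0.72) and −2.13 in cREL over 26 genes (1.66 ± 0.21 against 3.77 ± 0.63), with adjusted p = 1.5e-04, 4.1e-04 and 7.2e-05. Every gene of each set was smaller in these knockouts. In RELB the difference was −0.10 over 14 genes (4.51 ± 0.003 against 4.54 ± 0.70; adjusted p = 0.936), and 9 of 14 genes were smaller. Within batch B, a check chosen after the result was seen, with 1 clone of each genotype, the differences were −1.33 in p50, −1.12 in p52, −1.26 in cREL and 0.75 in RELB, and within batch C that of p65 was −2.72.

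**Figure D4:**
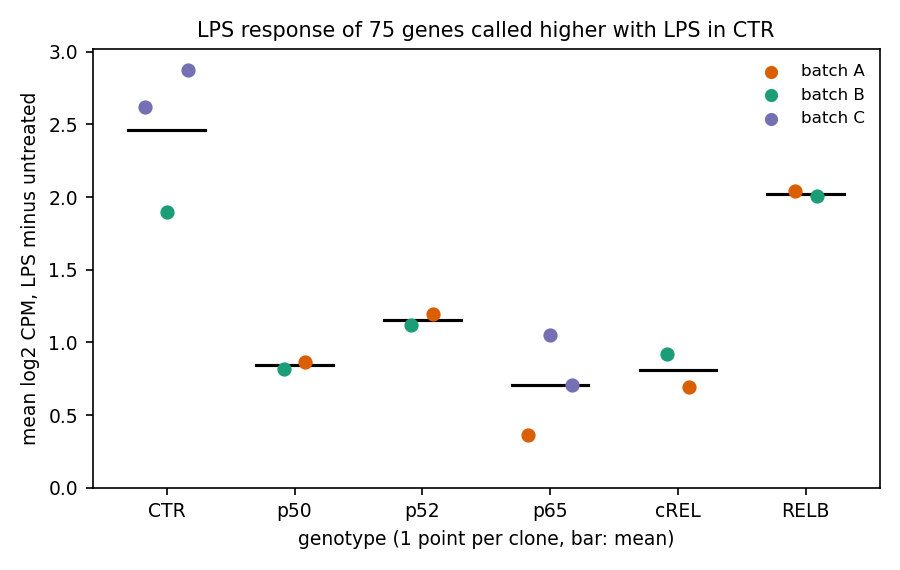
Mean log2 LPS-minus-untreated difference over the 75 genes called higher in CTR, for each of the 14 clones, coloured by sample batch. The RELB clones sit at 2.04 and 2.01 and the other knockout clones between 0.36 and 1.20; the genes were chosen in CTR, so the control values (1.90 to 2.87) are biased upward.

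Without LPS, few genes separated the knockouts from CTR. In p65, CCL2, a chemokine for monocytes, fell from 92.1 ± 35.1 to 10.4 ± 3.92 CPM (SD, n = 3; log2 fold −3.39 ± 0.49, SE; edgeR adjusted p = 0.00875). PTPN14 (−1.44), DCTN6 (−1.39) and AC009086.2 (−8.40) were also lower, and PGGHG (1.83), ALDH4A1 (1.21), PLCG2 (1.19), CCNA1 (1.07), ULK3 (1.04) and EHMT2 (1.00) were higher. The p65 clones did not overlap the controls for any of these genes except CCNA1 and EHMT2, and AC009086.2 was not compared by clone; 1 of the 3 is the clone labelled p65 replicate 1. The chemokine list had a median of −1.37, with 1 of 20 lower over all genes and 4 adjusted over the list alone, and its call was lost with an estimated correlation (adjusted p = 0.0594). edgeR called 10 genes in p65. The count was 4 without CTR replicate 1 or 2, 2 without p65 replicate 1, 400 without p65 replicate 2, 1 without p65 replicate 3 (whose untreated library had the lowest granule gene mean of all libraries, 5.36 log2 CPM), 0 in batch C alone, 2 without a batch term and 3 with an effective length offset.

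In RELB without LPS, 2 genes were higher, MST1 (36.8 ± 11.4 against 10.8 ± 3.08 CPM, SD; log2 fold 1.90 ± 0.28, SE; edgeR adjusted p = 0.0143) and RAPGEF4 (4.48). The cholesterol synthesis genes were higher as a list, with a median of 0.50, 16 of 19 higher by sign, 0 over all genes and 7 adjusted over the list alone (estimated correlation, adjusted p = 0.0114). MHC class II genes had a median of 2.53 and proliferation genes of −0.51, and these calls were lost with an estimated correlation (adjusted p = 0.193 for each). The RELB count was 8 without CTR replicate 1, 1 without a batch term and 4 with DESeq2's size factors. With an effective length offset it was 1, and neither MST1 nor RAPGEF4 kept its call. For p50, p52 and cREL edgeR called 0 genes without LPS, with 1196, 1416 and 1077 at an unadjusted p under 0.05; DESeq2 called 41, 62 and 24, and limma voom 1, 3 and 1. Without p50 replicate 1 the p50 count was 55 and without cREL replicate 1 the cREL count was 18. Leaving out a control clone gave at most 3 genes in these 3 comparisons, the 3 being in p52 without CTR replicate 1.

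With LPS, more genes were called between p65 and CTR than for the other knockouts, which have 2 clones where p65 has 3. Chemokine genes were lower: CCL2 stood at 25.8 ± 9.93 against 737 ± 335 CPM (SD, n = 3; log2 fold −4.94 ± 0.51, SE; edgeR adjusted p = 4.6e-05), CXCL8 at 125 ± 79.1 against 1069 ± 639 CPM (−2.72 ± 0.40; edgeR adjusted p = 0.00153) and CCL4 at 1.26 ± 1.02 against 84.3 ± 46.3 CPM (−6.05 ± 0.42). CCL8 had 3 counts over the p65 group and 686 over CTR, a ratio of 239 with a counting interval from 81.5 to 1163. Cytokine genes IL1B (−3.88) and TNF (−2.44), the feedback genes NFKBIA (−2.08), TNFAIP3 (−2.57), TNIP3 (−4.45) and NFKBIZ (−1.68), the surface molecules ICAM1 (−2.60), TNFRSF9 (−3.08) and CD44 (−1.002), and SOD2 (−3.47), PTGS2 (−3.48), SLC2A3 (−1.76) and IRAK2 (−1.20) were lower. Among called genes with a mean of at least 5 CPM and a gene symbol, those with the largest higher values were C11orf49 (2.76), IL17RE (2.08), ATG16L2 (1.86), ABHD8 (1.72) and IPO13 (1.65). Each of the 3 p65 libraries, which include the library labelled p65 replicate 1, lay beyond all 3 controls for every gene named so far here except ABHD8 and IPO13.

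By list, 11 of 20 chemokine genes were lower in p65 with LPS over all genes and 15 adjusted over the list alone, with a median log2 fold of −3.97 (estimated correlation, adjusted p = 8.1e-06). The same held for 5 of 18 cytokine genes and 10 adjusted over the list alone (median −2.34, adjusted p = 7.9e-05), 7 of 17 feedback genes and 8 over the list alone (−1.21, adjusted p = 6.7e-04), 5 of 18 adhesion genes and 8 over the list alone (−0.88, adjusted p = 2.4e-04) and 3 of 16 antimicrobial genes and 7 over the list alone (−1.18, adjusted p = 0.00174). Of 20 survival genes 2 were lower, and 7 lower and 1 higher adjusted over the list alone (−0.36, adjusted p = 6.7e-04), and of 29 TLR4 signalling genes 1 was lower and 8 adjusted over the list alone (−0.30, adjusted p = 0.0155). Of 47 interferon-stimulated genes 6 were lower, IFIT2 (−4.99) and IFIT3 (−4.63) among them, and 38 adjusted over the list alone. Their list call was lost with an estimated correlation (median −2.42, adjusted p = 0.0608), CTR replicate 2 lay within the p65 range for CXCL10, IFIT2 and IFIT3, and without CTR replicate 1 the median was −0.64, 0 were called by edgeR and the list passed narrowly (estimated correlation, adjusted p = 0.0497).

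edgeR called 185 genes in p65 with LPS, 63 higher and 122 lower. The count was 98 without CTR replicate 1, 74 without p65 replicate 1, 95 without p65 replicate 3, 65 (4 higher, 61 lower) without a batch term and 9, all lower, in batch C alone.

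With LPS, CCL2 was also lower in p50 (36.9 ± 13.3 CPM, SD, n = 2; log2 fold −4.40 ± 0.62, SE; edgeR adjusted p = 0.00927), p52 (27.4 ± 2.40 CPM; −4.78 ± 0.63; edgeR adjusted p = 0.00538) and cREL (32.4 ± 3.84 CPM; −4.55 ± 0.63; edgeR adjusted p = 0.00461), against 737 ± 335 CPM (SD, n = 3) in CTR. The glucose transporter gene SLC2A3 was lower by −1.62, −1.90 and −1.95, and CSF2RB, the common beta chain of the GM-CSF, interleukin-3 and interleukin-5 receptors, by −1.67, −1.25 and −1.41 (chosen after its values were seen for p50 and cREL). These comparisons share the control libraries, so their values are not independent of each other. In p50, CXCL8 (−2.77), ICAM1 (−1.998), the kinase gene PIM1 (−2.83), NID1 (−3.88), NCK2 (−2.26), TRIB3 (−1.89) and INSIG1 (−1.46) were lower and ALDH4A1 (1.06) higher. In p52, RGL1 (−2.06), STARD4 (−1.70) and DENND5A (−1.41) were lower and PRXL2A (2.09), MST1 (1.63), ALDH4A1 (1.29) and DOP1B (1.20) higher. In cREL, TNF (−2.98), IL1B (−3.45), TNFRSF9 (−3.25), CXCL8 (−2.64), SOD2 (−2.23), ICAM1 (−1.78), CD44 (−1.25) and IRAK2 (−1.10) were lower, SLAMF1 had 2 counts against 411 (ratio 137, counting interval 37.8 to 1138), and ERLIN1 (1.05), FAM173B (1.03) and PLCG2 (1.01) were higher. For every gene named here, the 2 knockout libraries lay beyond all 3 controls.

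Chemokine genes were lower as a list in p50, p52 and cREL (medians −1.47, −1.10 and −1.90; estimated correlation, adjusted p = 0.00412, 0.0125 and 0.00256), with 2, 1 and 2 of 20 lower over all genes and 8, 6 and 10 adjusted over the list alone. So were cytokines (−1.23, −1.63 and −1.83; adjusted p = 0.00412, 0.00557 and 0.00215; 0, 0 and 2 of 18, and 7, 5 and 5 adjusted over the list alone) and NF-kB feedback genes (−1.14, −0.68 and −1.28; adjusted p = 0.00412, 0.0323 and 0.00454; 0 of 17 in each, and 11, 1 and 8 adjusted over the list alone). Adhesion genes were lower too (−0.65, −0.75 and −0.66; adjusted p = 0.00947, 0.0323 and 0.00256), and in p50 the cholesterol synthesis genes (median −0.40, adjusted p = 0.0216; 1 of 19, and 5 adjusted over the list alone). Proliferation genes in p52 had a median of −0.38, and that call was lost with an estimated correlation (adjusted p = 0.223). The interferon-stimulated genes had medians of −1.75, −1.50 and −1.71 and their calls were lost likewise (adjusted p = 0.2, 0.351 and 0.207). Without CTR replicate 1 the medians were −0.46, −0.29 and −0.59.

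With LPS, edgeR called 24 genes in p50 (3 higher, 21 lower), 13 in p52 (7 higher, 6 lower) and 37 in cREL (5 higher, 32 lower). In p50 the count was 6 without CTR replicate 2, 11 without CTR replicate 3, 76 without p50 replicate 1 and 1 without p50 replicate 2. In p52 it was 24 without CTR replicate 1, 6 without CTR replicate 2 and 0 without either p52 clone. In cREL it was 10 without CTR replicate 2, 18 without CTR replicate 3, 19 without cREL replicate 1 and 1 without cREL replicate 2. Without a batch term the counts were 11, 2 and 13, and with an effective length offset 11, 7 and 19; limma voom called 22 in p52.

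In RELB with LPS, the cholesterol synthesis genes were higher than in CTR. By sign, 17 of 19 genes were higher (median 0.61; 1 over all genes and 10 adjusted over the list alone; estimated correlation, adjusted p = 5.5e-04). GM2A stood at 108 ± 15.8 against 42.8 ± 2.41 CPM (SD, n = 2 and n = 3; log2 fold 1.29 ± 0.21, SE; edgeR adjusted p = 0.0435; higher in 2 of 2 clones). PLAU (1.14), MST1 (1.56), MFAP4 (1.86) and RAPGEF4 (6.63) were also higher, and EZH2 (−1.25), a histone methyltransferase, CDC42EP3 (−1.42) and the pseudogene LSM12P1 (−9.90, chosen after its value was seen) lower. MHC class II genes had a median of 2.33, with 0 of 13 called over all genes and 6 higher and 1 lower adjusted over the list alone, and that call was lost with an estimated correlation (adjusted p = 0.153). The same was so for monocyte differentiation (median 0.63, adjusted p = 0.133) and proliferation (median −0.44, adjusted p = 0.162). edgeR called 9 genes, 6 higher and 3 lower. The count was 20 without CTR replicate 1, 5 without CTR replicate 2, 4 without CTR replicate 3, 57 without RELB replicate 1, 90 without RELB replicate 2, 5 without a batch term and 2 with an effective length offset.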

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

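The differences below came from tests fixed before the data were examined. In the difference of LPS response between p65 and CTR, 3 genes passed, all smaller in p65: ICAM1 (−2.26), PTGS2 (−4.47) and SOD2 (−3.15). Over the LPS-induced sets chosen without CTR and without the knockout in question, the mean response was lower than in CTR by a log2 difference of −1.97 in p50, −1.81 in p52, −2.50 in p65 and −2.13 in cREL.

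List medians of the same difference were as follows. In p50 they were −0.8716 for NF-kB feedback, −1.406 for cytokines, −2.155 for chemokines, −0.5201 for adhesion, −0.2031 for survival, −0.3407 for TLR4 signalling and −0.5643 for immediate early genes. In p52 they were −0.704 for feedback, −1.439 for cytokines, −1.678 for chemokines, −0.5703 for adhesion, −0.2107 for survival and −0.7008 for antimicrobial genes. In p65 they were −1.017 for feedback, −1.228 for cytokines, −1.775 for chemokines, −0.6153 for adhesion, −0.2462 for survival, −0.2334 for TLR4 signalling, −0.5924 for antimicrobial and −0.3394 for immediate early genes. In cREL they were −1.104 for feedback, −1.157 for cytokines, −1.795 for chemokines, −0.7094 for adhesion, −0.1085 for survival, −0.3936 for TLR4 signalling, −0.5799 for antimicrobial and −0.5551 for immediate early genes. These medians share the control libraries and so are not independent of each other. With each clone as a block, the calls for TLR4 signalling and immediate early genes in p50 (adjusted p = 0.0664 for each), feedback and chemokines in p52 (0.0945 and 0.0569) and chemokines and immediate early genes in p65 (0.0846 for each) were lost.

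Regroupings of the 3-clone arms were written before the data were examined, and such splits are too few for a share under 0.05. All 10 splits of the 6 libraries or clones, the true grouping included, were fitted. In p65 against CTR with LPS, the true grouping gave 185 genes and the highest other split 1; without LPS the values were 10 and 1, for the p65 minus CTR difference 3 and 1, and for LPS in CTR 76 and 1. For LPS in p65 the true grouping gave 5 genes and 1 other split gave 59, so 2 splits reached the true count. Because the clones pair the libraries, the closer comparison is with the splits that part all 3 pairs, of which there are 4: among these the highest other count was 0 in p65 and 0 in CTR. The split with 59 genes parts 1 pair only, with both libraries of the clone labelled p65 replicate 1 and the untreated library of replicate 3 on the same side. It points to a structure of the samples, and the cause was not tested. The untreated library of p65 replicate 3, which also enters the p65 results without LPS and the differences, had the lowest mean log2 CPM of all libraries for promyelocyte granule genes (5.36, the next 6.05) and MHC class I genes (5.003, the next 5.541), and 9.46 for mitochondrial messenger RNA against 9.97 in its LPS partner. These values were looked up after the result was seen. For p65 against the other 4 knockouts, 30 of the possible splits were used, the true grouping included, which is fewer than planned. Each gave 0 genes. Because any split reaches a true count of 0, these splits decide nothing.

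Pattern A, weighed with tests chosen after the result was seen, was that over the 75 genes called higher in CTR the RELB clones had a larger LPS response, 2.02 ± 0.03 (SD, n = 2), than the other knockout clones, whose response was smaller but present, 0.859 ± 0.254 (SD, n = 9). For interferon-stimulated genes the mean response was 0.01 and 0.09 in the RELB clones and 0.37 to 2.09 in CTR, a difference that did not pass with an estimated correlation (adjusted p = 0.705). Sample batch was excluded, because the smaller of the gaps within batches A and B was 1.05, and so was TLR4 messenger RNA below that of CTR, because the other knockouts stood at 1.10 times CTR without LPS (and at 0.782 times RELB, whose mean was 38.5 ± 14.3 TPM, SD, n = 2). An exact permutation test could not decide on chance, because the clones were singled out from the values it used. The exact permutation p = 0.0182 was thereby fixed at the smallest possible. RELB responded more than the mean of p50, p52 and cREL in 72 of 75 genes (camera, estimated correlation, p = 2.99e-05). Over 31 genes called in a fit of the control libraries alone, 30 were larger (camera, estimated correlation, p = 4.63e-05). There the lowest RELB clone was 2.70 and the highest other 1.51. Over all genes, edgeR called 1 in this contrast. This contrast was also chosen after the result was seen, and RELB was singled out from the responses of the same clones. These values therefore do not decide on chance among the knockout clones. Incomplete knockout of RELB remained open, since only 2 of 4 RELB libraries had RELB messenger RNA below the lowest control. Incomplete knockout cannot be told apart from a small role of RELB in these genes.

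Pattern B, also weighed with tests chosen after the result was seen, was that interferon-stimulated genes rose with LPS in CTR replicates 1 and 3 and little in CTR replicate 2. For the level without LPS, batch was excluded only as the source of the gap between CTR replicates 1 and 3. Replicate 1 exceeded replicate 3, which shares batch C, by 1.89 log2 units. Whether batch contributed to the level of CTR replicate 2 cannot be told from this gap. For the response, batch remained open, because the lower of the batch C responses exceeded that of the batch B control by 0.792. Interferon beta messenger RNA was in line with the pattern: IFNB1 had 13 estimated counts with LPS in CTR replicate 1, 6 in replicate 3 and 0 in replicate 2. Without LPS it had 0 counts in CTR replicate 1, although the interferon-stimulated genes stood higher there than in replicate 3. IFNB1 exceeded 3 counts in 2 of 28 libraries.

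Pattern C was that the libraries labelled p65 replicate 1 held RELA above every other library in TPM. It was weighed with tests chosen after the result was seen. In CPM these libraries, at 53.6 and 58.3, lay within the other genotypes, so the excess depends on the length scaling. A control clone under the wrong label was excluded, because the LPS response of this clone over the independent set was 0.526 and the lowest control clone reached 3.34. A swap with a clone low in RELA messenger RNA was excluded, because no library of another genotype held RELA below 23.2 TPM. A p65 clone that keeps its RELA messenger RNA would not be seen by this test. Batch was excluded for the TPM level, because the highest RELA value among the other batch A libraries was 37.5 TPM. A swap with another knockout clone, a wrong label on this clone alone and a mutation that leaves the messenger RNA in place cannot be told apart here.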

How the results depend on the processing

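The alternatives below were fixed before the data were examined, except the within-batch sets, the fit of control libraries alone and the omission of CTR replicate 1 for interferon-stimulated genes, which were chosen after the results were seen. The cause of each shift was not tested.

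DESeq2 called more genes throughout. With LPS it called 155 in CTR, 10 in p50, 14 in p52, 8 in p65, 8 in cREL and 58 in RELB. Against CTR without LPS it called 41 (p50), 62 (p52), 319 (p65), 24 (cREL) and 218 (RELB), and with LPS 236, 267, 650, 229 and 216. For the differences it called 6, 7, 19, 4 and 3, and 2 for p65 against the other knockouts. Without a filter on low counts, 38219 genes were tested and edgeR called 252, 39, 74, 32, 28 and 92 with LPS in CTR, p50, p52, p65, cREL and RELB. Against CTR the counts were then 172, 157, 995, 129 and 538 without LPS and 400, 347, 992, 364 and 436 with LPS. The differences gave 80, 75, 89, 69 and 34, and 27 for p65 against the other knockouts.

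Without a batch term the counts with LPS were 50 in CTR, 1 in p52, 0 in p65, 1 in cREL and 14 in RELB. Against CTR they were 2 (p65) and 1 (RELB) without LPS, and 11, 2, 65, 13 and 5 with LPS for p50, p52, p65, cREL and RELB. With an effective length offset they were 3 (p65) and 1 (RELB) without LPS, 11 (p50), 7 (p52), 19 (cREL) and 2 (RELB) with LPS, and 1 for the p65 difference. limma voom called 1, 3 and 1 in p50, p52 and cREL without LPS and 22 in p52 with LPS. In batch C alone p65 had 0 genes without LPS, 9 with LPS and 0 in the difference. DESeq2 size factors gave 4 genes in RELB without LPS. All shifts of the median fold from scaling were under 0.1.

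With each clone as a replicate block, the paired counts with LPS were 236 in CTR, 6 in p50, 5 in p52, 3 in p65, 4 in cREL and 81 in RELB. The paired differences gave 2 genes in p50, 1 in p52, 14 in p65, 0 in cREL, 0 in RELB and 1 in p65 against the other knockouts. Of 61 named calls 58 held. Among lists that passed with an estimated correlation, the block ended TLR4 signalling and immediate early genes in the p50 difference (adjusted p = 0.0664 for each), feedback and chemokines in the p52 difference (0.0945 and 0.0569) and chemokines and immediate early genes in the p65 difference (0.0846 for each). It added antimicrobial genes in the p50 difference (adjusted p = 0.037). Apart from these and those given with the results, the block changed no other call made with an estimated correlation.

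Leaving out each clone in turn gave these lowest and highest counts with LPS: 21 to 72 in CTR, 1 to 3 in p50, 1 to 1 in p52, 0 to 4 in p65, 1 to 2 in cREL and 8 to 11 in RELB. Against CTR without LPS they were 0 to 55 (p50), 0 to 3 (p52), 1 to 400 (p65), 0 to 18 (cREL) and 2 to 108 (RELB). With LPS they were 1 to 76, 0 to 24, 74 to 203, 1 to 32 and 4 to 90. The differences gave 0 to 2 (p50), 0 to 0 (p52), 0 to 3 (p65), 0 to 1 (cREL) and 0 to 1 (RELB), and 0 to 1 for p65 against the other knockouts. The mean over the independent LPS-induced set ran from −2.37 to −1.70 in p50, −2.23 to −1.53 in p52, −2.92 to −2.21 in p65, −2.49 to −1.89 in cREL and −0.46 to 0.13 in RELB. Within batch B it was −1.26 in cREL and 0.75 in RELB. The gap between RELB and the p50, p52 and cREL clones was 1.39 over genes called in a fit of the control libraries alone, against 1.09 over those called in all libraries.

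No named gene changed sign in a setting where it was called with the main model or with the alternative. Sign changes did occur among results called with neither. They numbered 42 of 1225 named results without a single clone, 9 of 269 with a length offset and 6 of 269 without a batch term, and fewer in each other setting. Of 160 named calls DESeq2 kept 160, other size factors 156, no filter 157, a length offset 117 and no batch term 84, and batch C alone kept 6 of 57. Without a single clone fewer held: 1 of 17 without cREL replicate 2, 3 of 17 without cREL replicate 1, 1 of 15 without p50 replicate 2, 7 of 15 without p50 replicate 1, 1 of 14 without either p52 clone, 29 to 43 of 61 without a p65 clone, 10 and 15 of 25 without a RELB clone and 72 to 80 of 130 without a control clone. limma voom kept 85 of 99. Of 396 list tests, 76 lost a preset-correlation call with an estimated correlation. With 2 or 3 clones per genotype and a biological coefficient of variation of 31.7%, changes of log2 1 were mostly missed in the simulation. There 8 to 35 of 100 were recovered, without clone or batch effects. A count of 0 therefore does not show that expression was unchanged.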

Other observations

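The tests on the set of 75 genes, on CD14 and on interferon were chosen after the results were seen. CD14, the co-receptor that hands LPS to TLR4, was read outside the naming rule. With LPS it stood at 7.24, 6.03 and 4.38 TPM in the control clones and at 3.50 and 2.54 TPM in RELB, whereas no clone of the other knockouts exceeded 0.647 TPM. Without LPS it ran from 0 to 1.53 TPM in the control clones and from 0 to 0.906 TPM in the p50, p52, p65 and cREL clones. In RELB it was then 0.734 and 0.872 TPM. The LPS effect on CD14 in CTR did not pass the test (log2 fold 3.12, edgeR adjusted p = 0.692, CD14 higher in 3 of 3 clones). The messenger RNA of TLR4 itself stood without LPS at 30.1 ± 5.72 TPM in the p50, p52, p65 and cREL clones (SD, n = 9), 27.4 ± 5.45 TPM in CTR (SD, n = 3) and 38.5 ± 14.3 TPM in RELB (SD, n = 2). LY96, a member of the TLR4 signalling list, was also read outside the naming rule. Without LPS it stood at 18.4 and 1.7 TPM in the RELB clones. It ran from 2.78 to 4.93 TPM in CTR and from 0.201 to 4.95 TPM in the p50, p52, p65 and cREL clones.

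MHC class II genes varied by clone and not by genotype alone. Their mean log2 CPM was 4.90 to 6.07 in the RELB libraries and 2.13 to 3.68 in CTR. In cREL it was 4.14 and 4.39 in replicate 1 but 1.22 and 1.72 in replicate 2. The list did not pass in RELB with an estimated correlation (adjusted p = 0.153 with LPS).

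Loss of p50, p52, p65 or cREL may weaken the LPS response through a shared step. In each of the 4 knockouts the independent set responded less than in CTR, and the gap between RELB and the p50, p52 and cREL clones within a batch was at least 1.05. A lower CD14 level could contribute, since CD14 with LPS was low in the same clones. Without LPS, however, CD14 was low in all clones and its level did not separate these knockouts from CTR. CD14 was also higher with LPS than without in each control clone and so could equally be a result of the weaker response. Adding back CD14 to p50 knockout clones and measuring CXCL8 and IL1B at 6 h would separate these.

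RELB may be dispensable for the 6 h response of the 75 genes called higher in CTR, or the RELB clones might still make RELB protein. The mean response of interferon-stimulated genes was 0.01 and 0.09 in the RELB clones, against 0.37 to 2.09 in CTR, but this difference did not pass with an estimated correlation (adjusted p = 0.705; 0.677 without CTR replicate 1), so whether RELB matters for them was not settled. The RELB libraries below the lowest control numbered 2 of 4, which leaves incomplete knockout of RELB open. A protein blot for RELB in the 2 clones would settle it, as would the sequence at the cut site.

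The interferon response in CTR replicates 1 and 3 may come from interferon beta made at low level. IFNB1 had at least 6 counts with LPS in these clones and 0 in CTR replicate 2. Without LPS the interferon-stimulated genes were already higher in CTR replicate 1 than in replicate 3, by 1.89 log2 units. IFNB1 had 0 counts in that library, so its messenger RNA does not account for that level. Batch C could instead have set the response, because the 0.792 gap between the batch C and batch B controls follows batch. The batch C controls also differed from each other, at 2.09 and 1.17. The p65 clones of batch C responded at 0.14 and 0.19, below the batch B control at 0.37, but these are knockouts. Without CTR replicate 1 the median response of these genes in CTR was 0.58 and that of p65 against CTR with LPS −0.64, and these lists passed with an estimated correlation (adjusted p = 0.028 and 0.0497). More control clones in each batch, with interferon beta measured in the medium, would decide between the 2 explanations.

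The clone labelled p65 replicate 1 might carry a RELA mutation that spares the messenger RNA, since its LPS response over the independent set was 0.526, below that of every control clone. The p50, p52 and cREL clones also lay below every control over that set, at 1.775 to 2.349. The low response therefore does not single out a RELA mutation. Reads across the guide site, or a p65 blot, would test for such a mutation. Without this clone the count against CTR with LPS was 74, but that of LPS in p65 was 4 and the mean difference over the independent set was −2.21.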
